A study of Mus musculus with 6 samples.

How the data were processed

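ATAC-seq libraries were made from granulocyte-monocyte progenitors sorted by flow cytometry from mouse bone marrow, with transposition by a Nextera kit, per the labels' protocols. The 6 libraries fell into 2 genotypes of 3, GFI1-KI and GFI1-KD, each numbered 1 to 3. In the table the columns of the first genotype carry the name WT. They were taken as GFI1-KI 1 to 3, because the series title calls the genotype that is not low in GFI1 wild type and the numbers match.

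The deposited values are normalized read counts per consensus peak, a coverage signal that the authors obtained by multiplying each library's counts by 1 factor, as far as the values show. The submitters' processing notes name Trim Galore, BWA, SAMtools, Picard, MACS2, DiffBind, ChIPseeker and HOMER and the build mm10, with no versions, roles or order. How peaks were merged, how the factors were computed and whether reads were shifted for the transposase offset are not given in the sources used here. A fixed consensus set means that absence of a peak in 1 library is a low value, not a missing row. Within each column every value was a whole multiple of 1 step (100% at a tolerance of 0.01 reads), so the reads behind each value were recovered. Steps ran from 0.7552 to 1.2342 normalized reads per read, and a floor of 3 reads lay between 2.27 and 3.70 normalized reads.

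Chromosomes are coded 1 to 21 in the table. Over the 18 codes on which alphabetical and numeric order differ, the alphabetical order of chromosome names placed 14.9% of peaks within 1 kb of the end of a protein-coding gene, against 2.3% when read as chromosome numbers. The share was higher for each of these codes, and the alphabetical order was used. Genes came from RefSeq coordinates of 21887 protein-coding genes on the same build. This annotation held no strand, so transcription start sites were not used: a gene-end peak is a peak within 1 kb of either end of a protein-coding gene, in place of the promoter class planned. Each peak was assigned to the gene it overlapped or the nearest gene body within 50 kb, in place of the nearest start site, which gave 161484 peaks (88.6%) a gene. Exons, introns and untranslated regions were not told apart. An assigned gene need not be the gene a peak regulates. No genome sequence was used here, so the planned comparison of sequence motifs in changed peaks was not run.

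Peaks with a mean of at least 10 normalized reads were tested, which removed 11433 of 182166. GFI1-KD was compared with GFI1-KI by limma 3.58.1 (R 4.3.3) on log2(value + 1), with a variance trend and no replicate block, and p-values were adjusted by the Benjamini-Hochberg method over the 170733 tested peaks at a threshold of 0.05. Fold changes are on the log2(value + 1) scale and are given with standard errors. Gene lists were tested by camera in limma at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 19 lists. The lists were GFI1 targets, monocyte and dendritic, neutrophil, stem and leukaemia, mature macrophage, erythroid, megakaryocyte, B cell, T and NK cell, eosinophil with basophil and mast cell, DNA repair, p53 targets, glycolysis, oxidative phosphorylation, cell cycle, interferon response, AP-1 and immediate early, autophagy, and ribosomal protein. Some genes stand in several lists. The gene-end and Gfi1-flank comparisons used two-sided Fisher's exact tests. The tests, the lists and the rule for named peaks were fixed before the data were examined, except that the gene-end class and the assignment to gene bodies were set afterwards, with the planned distances of 1 kb and 50 kb.

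The peaks named are all tested peaks assigned to Gfi1, the 12 largest increases and 12 largest decreases among called peaks whose genotypes did not overlap (1 per gene, predicted genes left out), and the peak with the smallest p of each list, or the 3 smallest for the GFI1 target, monocyte and dendritic, neutrophil, and stem and leukaemia lists. This gave 61 peaks, of which 53 were called, and 2 of the called peaks are not reported here. Further list members are given by their counts of called peaks, and these members were chosen after their values were seen.

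The alternatives were other scalings, pseudocounts, filters and thresholds, a replicate block, robust variance estimation, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Alternatives chosen after seeing the data were a term for chromosome Y reads, thinning of reads to equal depth, leaving out windows dense in strong changes, assignment to the gene with the nearest end, lists without gene-end peaks, and lists of gene-end peaks, or of all others, against peaks of the same class. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

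Depth sets what can be seen. The median standard error of the log2 fold change was 0.34 for peaks with a mean of 10 to 20 and 0.09 for those at 250 or more, and 4.88% and 16.9% of these peaks were called. Counts were simulated for this comparison with 200 of 170733 peaks changed. There limma recovered 26.9% of the 1.5-fold, 58.2% of the 2-fold and 95.5% of the 4-fold changes (18, 39 and 63 peaks). It made 16 false calls, a larger share of its calls than the adjusted threshold is meant to allow. When no peak had changed it made 7 calls. The real comparison called 17872 peaks. With so few peaks changed, the adjustment asks for smaller p-values than in the data, so these recoveries do not measure sensitivity there. Replicates of a genotype differed by more than sampling noise in all pairs (chi-square per degree of freedom 1.23 to 2.03), so none was taken for a copy of another. Libraries made separately from 1 sample would differ so too, and the test does not show that they came from separate animals. Floors cover counting error only.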

Results

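Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in granulocyte-monocyte progenitors sorted from the bone marrow of untreated C57BL/6 mice. GFI1 is a zinc-finger transcriptional repressor of blood progenitors. In the GFI1-KI mice human GFI1 stands in place of the mouse gene, and in the GFI1-KD mice human GFI1 is expressed at 10-20%, per the labels. Each genotype was represented by 3 libraries, named here KI1 to KI3 and KD1 to KD3. The table analysed held 182166 consensus peaks with a median length of 250 bp. Between 19408373 and 27741446 reads lay in peaks in the GFI1-KI libraries and between 16022763 and 19857646 in the GFI1-KD libraries. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

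The libraries separated by genotype on the main axis of difference. The first principal component of the log2 values took 44% of the variance, with the GFI1-KI libraries between -111.3 and -47.8 and the GFI1-KD libraries between 79.6 and 99.3. Pearson correlations across peaks were 0.966 to 0.977 within GFI1-KI, 0.960 to 0.969 within GFI1-KD and 0.938 to 0.957 between genotypes. Peaks are not independent replicates. KI1 lay nearest to the GFI1-KD libraries on the first component, and its 19408373 reads in peaks lay within their range, unlike KI2 and KI3. The share of reads in gene-end peaks also separated the genotypes, at 36.7% to 37.8% in GFI1-KI and 35.1% to 35.5% in GFI1-KD. This axis therefore does not separate genotype from technical differences that go along with it. KI2 held 1 read on chromosome Y and KD1 held 0, which allows up to 3, while the other 4 libraries held 499 to 865. Libraries with and without chromosome Y reads were present in both genotypes.

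The targeted locus was examined first. Gfi1 lies on chromosome 5 from 107716655 to 107725805 (mm10), and 13 tested peaks were assigned to it, of which 5 changed. An adjoining pair of peaks outside the gene was higher in GFI1-KD. The peak from 107706230 to 107706574, 10.3 kb from the gene, rose from 72.4 ± 25.1 to 155.5 ± 32.0 normalized reads (SD, n = 3 per genotype), a log2 fold change of 1.12 ± 0.19 (SE, limma adjusted p = 0.000822). Its neighbour from 107705653 to 107706189 rose by 0.64 ± 0.12 (limma adjusted p = 0.00128). On the other side, the peak 1.1 kb outside the gene, from 107726689 to 107727045, changed by -0.78 ± 0.16 (limma adjusted p = 0.0038). Within the gene body, 1 peak rose by 0.41 and another changed by -0.38 on the log2 scale. The call of the rising gene-body peak was lost without KI2 (limma adjusted p = 0.131), KD1 (0.0509) or KD3 (0.0635), and that of the falling one without KD3 (0.0572). A peak 8.3 kb outside the gene, at 429 ± 76.4 against 531.4 ± 38.7 normalized reads, missed the threshold (limma adjusted p = 0.0534) and was called without KI1 (0.00236) and under other scalings. The pair of peaks within 1 kb of the gene's end at 107725805, with 244.2 ± 21.1 against 218.2 ± 19.6 and 668.3 ± 43.3 against 603.1 ± 20.8 normalized reads (SD, n = 3), did not pass the test. The mouse build holds no human GFI1 sequence, and accessibility does not measure GFI1 expression, so these peaks are no direct check of the genotype labels.

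**Figure D1:**
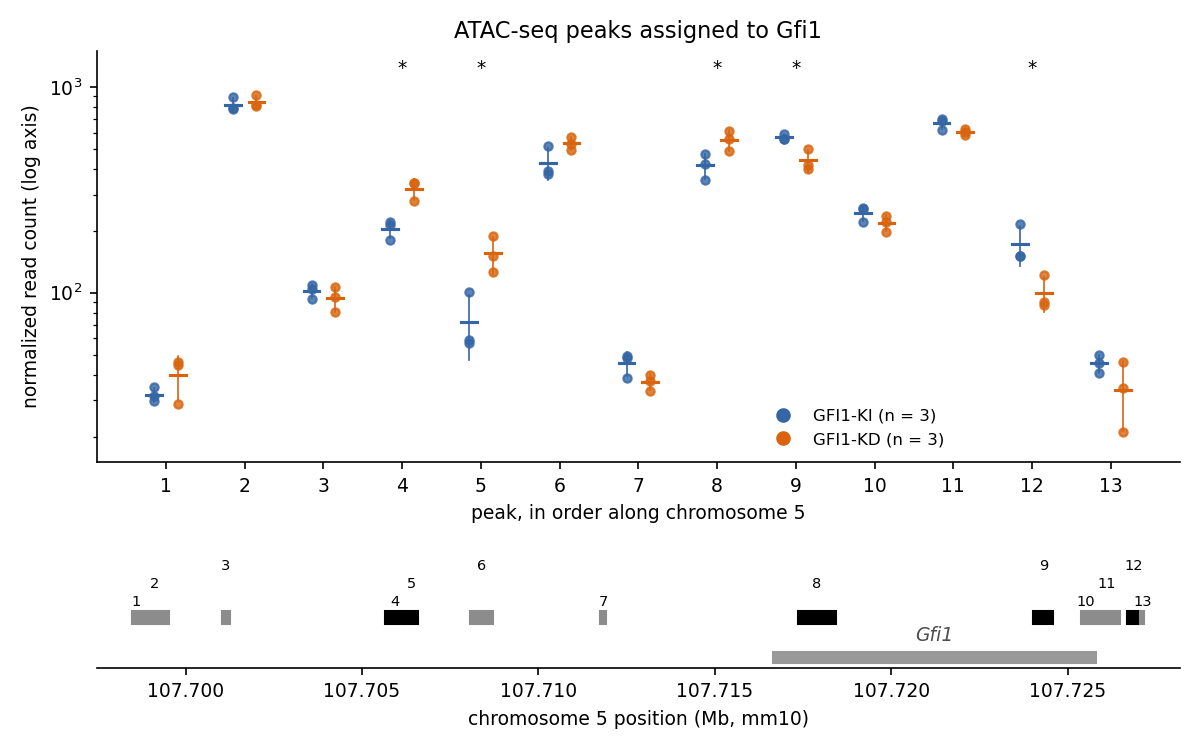
Normalized read count (log axis) of each of the 13 tested peaks assigned to Gfi1, with 1 point per library, the mean as a horizontal bar and the SD as a vertical line (n = 3 per genotype), above a map of the peaks along chromosome 5 in Mb. Asterisks and black boxes mark the 5 peaks with an adjusted p under 0.05, of which 3 were higher and 2 lower in GFI1-KD.

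Across the genome, low GFI1 was accompanied by changes in both directions. Of 170733 tested peaks, 17872 (10.5%) differed between GFI1-KD and GFI1-KI at an adjusted p under 0.05 in limma's moderated test. Among them 8520 were higher and 9352 lower in GFI1-KD, and 4843 changed at least 2-fold, 1902 higher and 2941 lower. The median absolute log2 fold change of the called peaks was 0.75. At an unadjusted p under 0.05 there were 43463 peaks. The 3 GFI1-KD values lay all above or all below the 3 GFI1-KI values in 95% of called peaks and in 28.8% of all tested peaks, against 10% by chance.

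The balance of directions depended on how the libraries were scaled. With the deposited scaling 47.7% of called peaks were higher in GFI1-KD, against 60% of 19421 with median-of-ratios scaling, 58.6% of 20152 with equal totals and 59.8% of 17117 with reads thinned to equal depth. The edgeR quasi-likelihood test on recovered reads called 21516 peaks (58.4% higher) and DESeq2 called 10819 (66.8% higher). Neither direction can therefore be called the more frequent. Without KI2, KI3 or KD3 the count fell to 7245, 6996 or 10807 peaks. Without KI2 the share of higher peaks was 59.4%.

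The largest single changes were near all-or-none. The most reduced peak lay inside Arhgap24, which encodes a GTPase-activating protein, on chromosome 5 from 102629255 to 102629773. It held 391.4 ± 73.6 normalized reads in GFI1-KI and 2.73 ± 1.98 in GFI1-KD (SD, n = 3; limma adjusted p = 3.25e-12), with 2, 4 and 1 reads in the GFI1-KD libraries. Inside Fras1, an extracellular matrix gene, a peak on chromosome 5 from 96758214 to 96758481 went from 58.1 ± 2.31 to 3.33 ± 2.16 (limma adjusted p = 1.31e-06). In the other direction, a peak inside Cops4, a subunit of the COP9 signalosome, on chromosome 5 from 100525727 to 100525980, held 1.55 ± 1.98 in GFI1-KI and 83.2 ± 19 in GFI1-KD (limma adjusted p = 2.98e-07). Peaks inside Avl9 on chromosome 6 (56757899 to 56758224) and Iqgap2, a scaffold gene of the IQGAP family, on chromosome 13 (95679747 to 95680121) rose from 2.88 ± 1.51 to 96.7 ± 8.15 and from 4.97 ± 1.57 to 141.3 ± 7.80. Peaks inside Ipo11, an importin gene, and Atg10, an autophagy gene, both on chromosome 13, rose by 3.63 ± 0.22 and 3.24 ± 0.24 on the log2(value + 1) scale, which understates changes from near 0.

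Of the 24 largest changes named by rule, 8 lay in 5 Mb windows dense in changes of at least 4-fold. Those inside Fras1, Iqgap2 and Trpc6 were among them, so they need not be changes of single peaks. On chromosome 8 lay 8 of the 24. Higher in GFI1-KD were peaks inside Dctn6, Sgcz and Csmd1, 14.4 kb from Micu3 and 1.5 kb from Stxbp2. Lower in GFI1-KD were peaks inside Rbpms, 25.9 kb from Lonrf1 and 16.8 kb from Gtf2e2. Several differed among the GFI1-KD libraries. The Rbpms peak held 247.2 ± 12.2 normalized reads in GFI1-KI but 2.1 in KD1, 98.7 in KD2 and 120.9 in KD3, and the Dctn6 peak held 77.0, 34.6 and 34.4 in KD1, KD2 and KD3 against 1.63 ± 1.42 in GFI1-KI. The Csmd1 peak held 104.9, 23.4 and 4.4 in the same order, and its call was lost without KD1 (limma adjusted p = 0.0953). The Stxbp2 peak held 56.7, 42 and 6.7 in that order, against 2.51 ± 2.64 in GFI1-KI. The Gtf2e2 call was lost without KI2 (0.0622), and that of Lonrf1 without KI1, KI2 or KI3 (0.0703, 0.0779 and 0.0651). DESeq2 and limma with robust variance estimation did not call Rbpms (adjusted p = 0.483 and 0.384) or Lonrf1 (0.691 and 0.454). Elsewhere, the peak near Sel1l on chromosome 12 was low in KD1 and KD2 alone, with 56.5 normalized reads in KD3 against 68.7 ± 6.08 in GFI1-KI, and neither DESeq2 (adjusted p = 0.579) nor robust variance estimation in limma (0.275) called it. Other named peaks with large changes held between 1.14 and 5.17 normalized reads on average in the lower genotype. Among them a peak 33.8 kb from Zfp710 was higher in GFI1-KD. Peaks inside Trpc6, Pik3c2g and Fhod3 were lower, as were those 15.4 kb from Slc28a2b, 46.6 kb from Prl2c1 and 10.1 kb from Plppr4. Of these, the Plppr4 call was lost without KI2 (limma adjusted p = 0.0565) and that of Prl2c1 without KI3 (0.0575).

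**Figure D2:**
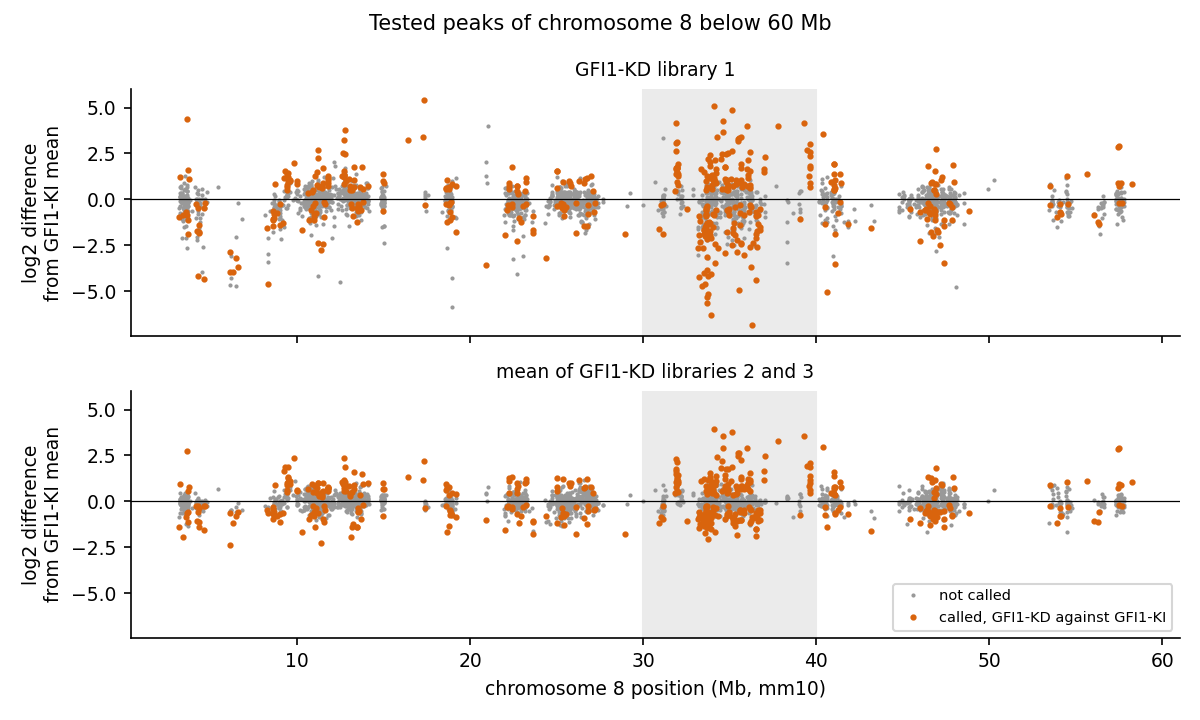
Log2 difference from the GFI1-KI mean of each tested peak of chromosome 8 below 60 Mb against position in Mb, for KD1 (upper panel) and for the mean of KD2 and KD3 (lower panel). Between 30 and 40 Mb (shaded), where 201 of 588 peaks were called, the median absolute difference was 0.66 in KD1, 0.41 in KD2 and 0.40 in KD3, against 0.25 to 0.28 elsewhere.

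Gene lists fixed in advance were then compared with all other peaks, each peak being assigned to the protein-coding gene it overlapped or to the nearest within 50 kb. Of 19 lists, 2 differed, both higher in GFI1-KD. The neutrophil list, with granule and receptor genes, had 130 tested peaks, of which 13 were higher, 3 lower and 114 not called (19 higher and 5 lower adjusted over the list alone). Its camera adjusted p was 0.0132 at a preset correlation of 0.01 and 0.847 with an estimated correlation. Of its 20 genes with a tested peak, 4 had called peaks that were only higher, 0 only lower and 3 both. No peak was called at the others, among them Elane, Prtn3, Ctsg, Cebpe, S100a8, S100a9, Ngp, Mmp9 and Ly6g. Mmp8, a neutrophil collagenase, had 4 of 9 peaks higher, and Fcnb, which encodes a ficolin, had 2 of 12. A peak inside Cxcr2, the chemokine receptor for neutrophil release, rose by 1.08 ± 0.21 on the log2 scale (limma adjusted p = 0.00242), with 1 of the other 9 Cxcr2 peaks lower. Against the list's direction, peaks inside Csf3r, the G-CSF receptor, and Ltf, lactoferrin, changed by -0.95 ± 0.19 and -1.27 ± 0.27, and Csf3r had 3 further peaks that were higher. Without KI2 or KD1 the neutrophil list was not called (adjusted p = 0.0525 and 0.0577), nor with peaks of mean 50 or more (0.0751) or gene-end peaks alone against all other peaks (0.0685), but it was called with gene-end peaks against other gene-end peaks (0.000358). Outside the 5 Mb windows dense in strong changes, of which the Mmp8 window on chromosome 9 is 1, it was called at 0.0486.

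The AP-1 and immediate early list had 273 tested peaks, 33 higher and 17 lower (38 and 19 adjusted over the list alone). Its camera adjusted p was 0.0166, and 0.847 with an estimated correlation. Dusp1, a MAP kinase phosphatase, had 7 of 17 peaks higher and none lower, with the strongest on chromosome 17 from 26509444 to 26509760 rising from 139.3 ± 17.0 to 306.5 ± 60.3 normalized reads (log2 fold change 1.12 ± 0.14, limma adjusted p = 4.14e-05). Egr2 had 4 of 11 peaks higher, Fos 3 of 37 and Batf 3 of 12, with none lower. Ier2 had 3 of 8 peaks lower and Egr1 2 of 8, with none higher. The list was not called without KI2 (adjusted p = 0.0525), with peaks of mean 50 or more (0.0751) or with 1 value per gene (0.0751). With gene-end peaks alone its direction turned, lower in GFI1-KD at an adjusted p of 0.0594 against all other peaks and of 0.633 against other gene-end peaks.

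**Figure D3:**
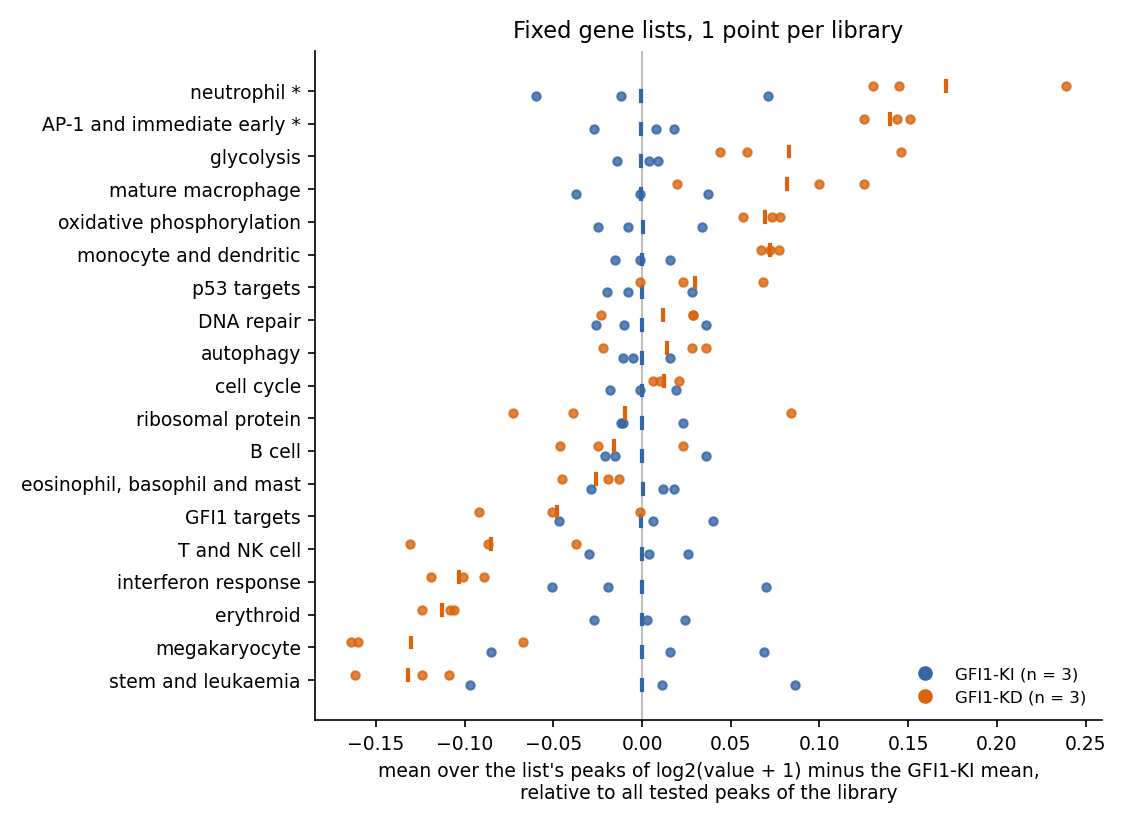
Mean over each list's peaks of log2(value + 1) minus the GFI1-KI mean, relative to all tested peaks of the same library, with 1 point per library and a bar at the genotype mean (n = 3). Asterisks mark the lists called by camera: the neutrophil list, with GFI1-KD libraries at 0.13 to 0.239 and GFI1-KI libraries at -0.06 to 0.071, and the AP-1 and immediate early list, at 0.125 to 0.151 against -0.027 to 0.018.

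The stem and leukaemia list, with self-renewal regulators, had 44 peaks lower and 12 higher of 524 tested (51 and 13 adjusted over the list alone) and missed the threshold (camera adjusted p = 0.0533, 0.847 with an estimated correlation). It was called lower in 9 of 29 alternatives, among them leaving out KI1 (adjusted p = 0.00738) or KD2 (0.0397), with a range of 0.00738 to 0.847. Hlf and Prdm16, transcription factors of stem cells, each had 8 peaks lower and none higher, of 27 and 31 tested. The strongest Hlf peak, on chromosome 11 from 90380044 to 90380380, went from 57.3 ± 8.81 to 16.7 ± 1.77 normalized reads (log2 fold change -1.71 ± 0.22, limma adjusted p = 6.64e-05). Mecom had 4 of 50 peaks lower and Kit, the stem cell factor receptor, 4 of 34 with 1 higher. A peak inside Erg changed by -2.00 ± 0.33, although 3 of the 60 Erg peaks were higher, and a peak inside Fli1 rose by 1.05 ± 0.17, although 3 of the 42 Fli1 peaks were lower.

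The monocyte and dendritic list had 25 peaks higher and 16 lower of 323 (31 and 18 adjusted over the list alone; camera adjusted p = 0.0905) and was called higher without KI1 (0.0485), with 1 value per gene (0.0352) and with gene-end peaks against other gene-end peaks (0.000358), with a range of 0.000358 to 0.847 over 29 alternatives. Tlr4, the lipopolysaccharide receptor, had 4 of 10 peaks higher, and the strongest rose from 23.0 ± 7.21 to 71.4 ± 9.33 normalized reads (log2 fold change 1.64 ± 0.23, limma adjusted p = 0.000144). Its co-receptor Cd14 had 3 of 7 peaks higher. A peak near Batf3, a dendritic cell factor, rose by 1.15 ± 0.17, and 1 inside Irf8, which directs progenitors to the monocyte and dendritic lineages, by 0.99 ± 0.16 (limma adjusted p = 0.000499). Zeb2 had 5 of 37 peaks lower and 1 higher.

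The list of GFI1 targets, gathered from background knowledge, was not called by camera, which tests for a net shift in 1 direction. Of 363 peaks 25 were higher, 31 lower and 307 not called (31 higher and 42 lower adjusted over the list alone), with a camera adjusted p of 0.527. Of all tested peaks 10.5% were called. The list includes the 13 peaks at Gfi1 itself, 3 higher and 2 lower. A peak 23.0 kb from Csf1, the macrophage growth factor gene, rose by 0.72 ± 0.11 (limma adjusted p = 0.00038), as did the Irf8 peak above. The peak 11.3 kb from Gfi1b, the paralogue of Gfi1, went from 312.9 ± 58.0 to 140.4 ± 58.1 normalized reads (log2 fold change -1.21 ± 0.19, limma adjusted p = 0.000376), with an adjusted p of 0.0564 under robust variance estimation.

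Lists of other blood lineages, which mark cells that a progenitor gate could hold, were not called with all peaks and libraries. The erythroid list had 7 peaks higher and 21 lower of 182 (12 and 32 adjusted over the list alone; camera adjusted p = 0.115), the megakaryocyte list 3 and 14 of 124 (5 and 14; 0.115), and the T and NK cell list 2 and 11 of 151 (2 and 9; 0.148). With gene-end peaks alone against all other peaks, 16 of the 19 lists pointed downward, against 11 with all peaks and 12 against other gene-end peaks. The erythroid and megakaryocyte lists were then called lower (limma camera adjusted p = 0.00729 for each), with 0.0387 and 0.0515 against other gene-end peaks. The erythroid list was also called lower with 1 value per gene (0.0352) and the megakaryocyte list without KI1 (0.0485), and over 29 alternatives both ran from 0.00729 to 0.847. A peak at Gp9, a platelet glycoprotein gene, changed by -1.44 ± 0.20. The mature macrophage list had 4 higher and 6 lower of 132 (3 and 5; 0.115, and 0.0371, higher, with gene-end peaks against other gene-end peaks), the B cell list 5 and 9 of 113 (7 and 9; 0.995), and the eosinophil, basophil and mast cell list 12 and 18 of 173 (15 and 22; 0.982). Leading peaks lay inside Mertk, a phagocytic receptor gene (0.92 ± 0.14), inside Blk, a B cell kinase gene (-1.16 ± 0.13), near Cd2 (1.19 ± 0.14) and inside Mitf (-1.40 ± 0.19).

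Metabolic, stress and housekeeping lists were not called with all peaks and libraries. Glycolysis had 21 peaks higher and 9 lower of 258 (22 and 9 adjusted over the list alone; camera adjusted p = 0.148), with a peak near Pdk1, a pyruvate dehydrogenase kinase gene, rising by 0.98 ± 0.13. Oxidative phosphorylation had 13 and 5 of 167 (13 and 5; 0.527), with a peak 22.5 kb from Cox4i1 rising by 0.94 ± 0.16. Interferon response had 1 and 4 of 112 (0 and 1; 0.0746), and was called lower without KI1 (0.0337) and with gene-end peaks alone (0.00956, but 0.0797 against other gene-end peaks). DNA repair had 10 and 6 of 144 (11 and 9; 0.9), p53 targets 6 and 11 of 194 (6 and 10; 0.886) and cell cycle 9 and 18 of 307 (7 and 16; 0.886). Autophagy had 10 and 10 of 194 (10 and 10; 0.9, with gene-end peaks alone 0.0319, lower, but 0.349 against other gene-end peaks) and ribosomal proteins 3 and 2 of 95 (3 and 0; 0.527). Leading peaks were inside Fanca (1.15 ± 0.22), 5.2 kb from Pmaip1 (1.43 ± 0.22), 0.2 kb from Ccnd2 (-0.52 ± 0.09) and 13.8 kb from Rpl11 (0.95 ± 0.22). For the B cell, p53 and oxidative phosphorylation lists the median log2 fold change was below 0 while the test pointed upward, and the mean was below 0 for the B cell and p53 lists.

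Peaks at the ends of genes seldom gained accessibility. Within 1 kb of either end of a protein-coding gene, 370 of 25221 tested peaks were higher and 1798 lower in GFI1-KD. Such peaks made up 4.34% of higher peaks, 19.2% of lower peaks and 14.8% of all tested peaks. Their odds ratio among higher peaks was 0.251 (95% interval 0.225 to 0.279, two-sided Fisher's exact test, p = 3.89e-222). Among lower peaks it was 1.40 (1.33 to 1.48, Fisher's exact p = 1.71e-33), but it fell to 0.986 with median-of-ratios scaling, 0.958 in edgeR and 0.990 in DESeq2, and to 0.883 without KI2 and 0.776 without KI3. Neighbouring peaks are not independent, so these tests are descriptive. The median log2 fold change was -0.10 at gene ends and -0.04 elsewhere. Gene-end peaks took 36.7% to 37.8% of reads in the GFI1-KI libraries and 35.1% to 35.5% in the GFI1-KD libraries.

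**Figure D4:**
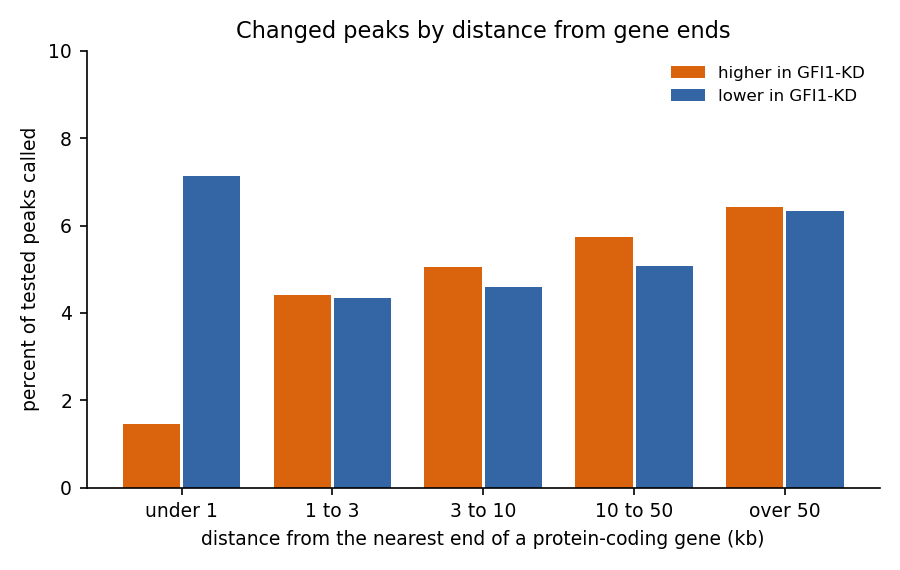
Percent of tested peaks called higher or lower in GFI1-KD (bars, from 0) by distance in kb from the nearest end of a protein-coding gene. Under 1 kb, 370 peaks were higher and 1798 lower, while at 10 to 50 kb 3451 were higher and 3051 lower.

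The chromosome around the engineered locus was compared with the rest of the genome, because the flank could carry sequence from the targeted cells. Within 10 Mb of Gfi1, 273 of 2138 tested peaks (12.8%) had changed, against 10.4% elsewhere (odds ratio 1.26, 95% interval 1.10 to 1.43, two-sided Fisher's exact test, p = 0.000638). Peaks inside Arhgap24 and Cops4, among the largest changes of all, lie within that distance. Read counts alone cannot tell an effect of low GFI1 on them from a difference in linked sequence. The difference was not called within 2 Mb (odds ratio 1.34, Fisher's exact p = 0.0605) or without KI1 (1.12, Fisher's exact p = 0.0647).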

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

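The depletion of gene ends among higher peaks kept its direction and call in all alternatives run, and 42 of the 53 called named peaks kept theirs in every alternative that tested them (19 to 22 each), with 0 reversed. A 2-fold minimum was not among these, and 32 of the 42 had changed that much. The chromosome Y term (19069 peaks), leaving out dense windows (17507) and thinning (17117) were chosen after seeing the data. The motif comparison and its alternatives were not run, because no genome sequence was used. Unless stated, the cause of a change was not tested.

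The count of called peaks fell to 10819 in DESeq2 and, by construction, to 4843 with a minimum of 2-fold (1902 higher, 2941 lower), and rose to 27678 at an adjusted p of 0.1 (15095 lower). Lower peaks numbered 3597 in DESeq2 and 5956 with a mean of at least 50, where fewer peaks were tested. Leaving out 1 library gave 6996 to 22129 peaks, 3604 to 11950 higher and 2940 to 10179 lower. The odds ratio of gene ends among lower peaks turned below 1 with median-of-ratios scaling (0.986), cyclic loess (0.947), quantile normalization (0.905), edgeR (0.958) and DESeq2 (0.990), and ran from 0.776 to 1.73 without 1 library, with 0.883 without KI2. Near Gfi1 the odds ratio was 1.34 within 2 Mb and 1.12 to 1.63 without 1 library. The number of lists called was 0 with a mean of at least 50, 0 with an estimated correlation, 5 with gene-end peaks alone, 4 with gene-end peaks against other gene-end peaks, 4 with 1 value per gene, and 0 to 6 without 1 library. The AP-1 list turned downward with gene-end peaks alone (adjusted p = 0.0594, and 0.633 against other gene-end peaks). Over 29 alternatives the adjusted p ran from 0.000358 to 0.847 for the neutrophil list and from 0.000334 to 0.847 for the AP-1 list, which were called in 24 and 23.

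With the replicate number as a block, 18940 peaks were called. Deviations of same-numbered libraries correlated at -0.02, -0.04 and 0.06, so the numbers do not pair the libraries, and only library 3 of GFI1-KI correlated best with its own number. Depth limits the weakest peaks: 4.88% of peaks with a mean of 10 to 20 were called.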

Other observations

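Beyond the fixed lists, changed peaks gathered at particular genes (counted after the calls were seen). At 182 genes 5 or more peaks had changed, all in 1 direction, 101 higher and 81 lower in GFI1-KD, against at most 26 in 100 shuffles of the calls among peaks of like height. Higher peaks gathered at Fndc3b (15 of 68 tested), Lpp (15 of 81), App, the amyloid precursor gene (11 of 30, median log2 fold change of the called peaks 0.93), Ccl2, a monocyte chemokine (10 of 11, 0.82), Socs3, an inhibitor of cytokine signalling (9 of 22, 0.69), and the immune surface genes Cd86 (6 of 21, 1.01) and Cd38 (6 of 14, 0.76). Lower peaks gathered at Nfia, a transcription factor (13 of 78, median of the called peaks -1.06), Sorcs2 (13 of 35, -1.10), Limch1 (11 of 26, -1.15), Zbtb16 (7 of 52, -1), Angpt1, a ligand of the TIE2 receptor (6 of 44, -1.02), and Ccnd2, which encodes cyclin D2 (6 of 21, -0.50). Between 72 (DESeq2) and 177 (quantile normalization) of the 182 genes had 5 or more peaks called in the same direction over 6 other scalings or tools, and at none did opposite calls outnumber them. In DESeq2 these were 63 of the 101 higher and 9 of the 81 lower genes. Neighbouring peaks are not independent, so the shuffles understate what chance gives.

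The tests of explanations below were chosen after the data had been seen, except that of other splits of the libraries, while the gene-end odds ratios under other scalings and without single libraries were planned as alternatives. For thinned reads the deciding bound was set before the result was seen. The 6 libraries allow 10 splits into 3 and 3, so no share under 0.05 can be had. The real split gave 17872 peaks, and it was the 1 split with as many, the highest other giving 0. It gave 2 lists, and 4 of the 10 splits gave as many, the highest other giving 2.

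Strong changes of at least 4-fold gathered on chromosome 8 between 30 and 40 Mb, which held 36 of 276 and where 34.2% of 588 peaks were called, against 10.4% elsewhere. A gain or loss of copies is argued against by a median log2 fold change of -0.09, with 104 peaks higher and 97 lower. An effect shared alike by all GFI1-KD libraries is argued against by the spread among GFI1-KD libraries, 1.6 times that among GFI1-KI libraries, where the 95th percentile of 482 other windows was 1.25 and the highest 2.08. Across peaks there, KD1 departed further in the direction in which KD2 and KD3 departed from GFI1-KI (r = 0.48, against a median of -0.31 in the other windows). KD1 did so less closely in 5 Mb windows of chromosome 8 starting at 0, 5, 15 and 40 Mb (0.23, 0.30, 0.32 and 0.34). The windows starting at 10, 20 and 45 Mb, between or beside these, had no positive r (-0.02, -0.06 and -0.06). Between 30 and 40 Mb, 6 peaks were down to at most 3 reads in KD1, of 298 with at least 40 normalized reads in GFI1-KI (elsewhere 13 of 91913). These 6 held on average 98.5 in GFI1-KI and 44.5 in KD2 and KD3. A candidate explanation is therefore a haplotype of another strain than the labelled C57BL/6. KD1 would then differ from GFI1-KI on both chromosomes, and KD2 and KD3 on 1. The values do not show whether GFI1-KD or GFI1-KI would carry the haplotype of the other strain. Genotypes would settle this hypothesis. KD1, with 0 chromosome Y reads against 499 and 618, came from other animals than KD2 and KD3. The 5 Mb windows dense in strong changes on chromosomes 5, 9 and 13 did not share the pattern (r = -0.25, -0.34 and -0.29). This r cannot show a haplotype carried alike by all GFI1-KD libraries, so such a haplotype in those windows was not tested.

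Among the called peaks at gene ends, most were lower in GFI1-KD (1798, against 370 higher), while most gene-end peaks were not called. A trend with peak height is argued against by the tallest 10% of peaks, where gene ends lay -0.10 (log2) from others after cyclic loess. Unequal depth is argued against by the odds ratio among lower peaks after thinning (1.29, lower bound 1.21), but for that scaling alone. Equal totals without thinning gave 1.29 too, and the ratio fell below 1 under other scalings. Gene-end calls were lower in at least 61.6% of cases under 6 other scalings or tools, which argues against scaling as the whole cause. The excess among lower peaks is less secure and its source stays open, since the odds ratio went down to 0.905 under another scaling and, with the deposited one, to 0.883 without KI2 and 0.776 without KI3. A lower ratio of signal to background in the GFI1-KD libraries cannot be told apart from a change at gene ends, because the share of reads in gene-end peaks was lower in all 3 GFI1-KD libraries, along with the genotype (difference -1.93 percentage points).

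The neutrophil and AP-1 lists were higher in GFI1-KD at the preset correlation alone. The erythroid, megakaryocyte and T and NK cell lists pointed lower, whereas carry-over of those cells would raise them. They lay at least 0.23 (log2) below the neutrophil list in every GFI1-KD library. The largest SD of a list among GFI1-KD libraries was 0.08, for ribosomal proteins, which ran from -0.073 to 0.084. The list values were known when this comparison was set, so it is no independent test of carry-over. A lack of gene-end peaks does not account for the higher neutrophil and AP-1 lists, as such peaks made up 21.5% of the neutrophil and 15.8% of the AP-1 list, against 14.8% of all tested peaks. Carry-over of myeloid cells, or a shift within the sorted gate toward the neutrophil lineage, cannot be told apart from a change per cell in bulk libraries: every GFI1-KD library lay above every GFI1-KI library for the neutrophil list (smallest gap 0.06) and for the monocyte and dendritic list (0.05). An effect of low GFI1 on these genes stays open as an untested hypothesis.

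Within 10 Mb of Gfi1 lay 7 of the 276 changes of at least 4-fold (odds ratio 2.06, 95% interval 0.818 to 4.30, two-sided Fisher's exact p = 0.0914). The 5 Mb windows of chromosome 5 starting at 90, 95, 100 and 105 Mb held 4, 6, 4 and 2, against 0.55, 0.4, 0.74 and 0.81 expected. Those starting at 110 and 115 Mb held 1 and 0, against 1.18 and 0.91. The window starting at 95 Mb was dense in such changes (Poisson adjusted p = 0.000677), and the 10 Mb limit cuts through it. The Fisher's test therefore does not exclude a gathering of strong changes near Gfi1.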
